A study of Homo sapiens with 22 samples.

How the data were processed

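SMARCA4, SMARCC1 and H3K27ac were profiled by CUT&Tag in AN3CA cells with an empty vector (2 replicates) or with 1 of 5 forms of ARID1A (1 library each), and the HA library analysed here was from DDX4 cells. Stamps at the start of peak names were read as sequencing runs, which the labels do not state. Samples were grouped by construct and antibody from their titles. Nuclei were handled by a commercial CUT&Tag protocol, per the labels' protocols. The build hg19 and the tool bcl2fastq, with no version, are named in the submitters' processing notes. The aligner, the treatment of duplicate fragments, the peak caller and any control library are not given in the sources used here.

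Each library had 1 deposited list in the 10-column narrowPeak layout, so peaks were called per library and replicates were not pooled. In the deposited lists the fold enrichment is a ratio of the pileup at the summit to the local background, each with 1 added. The authors also deposited a -log10 p-value and a -log10 q-value per peak, and the lowest -log10 q was 2.00 to 2.03 in every list, just above the value of 2 for a q of 0.01. The deposited score equalled 10 times the -log10 q, rounded down, in all but at most 3 peaks of a list. These values are the authors', belong to a peak within its own list, and were used only to describe, rank or filter peaks within that list.

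Total fragment numbers are not in the peak lists, so relative depth was derived from them. The fold and the p-value of a peak together fix its pileup and its background, taking the p-value as a Poisson tail, and whole pileups were recovered to within 0.001 in -log10 p for at least 99.75% of the peaks of every library. The lowest background of a library, shared by at least 73 of its peaks, divided by the length of its shortest peak as a stand-in for fragment length, gave fragments per kb. This depth is an estimate for comparing libraries of 1 antibody, and it does not measure the share of fragments in peaks.

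Peaks on chromosomes 1 to 22 and X were used, and peaks shared at least 1 bp to count as overlapping. BAF sites, gained sites and constitutive sites were defined as in the results, and a mutant kept a site when both a SMARCA4 and a SMARCC1 peak of that mutant overlapped it. Shares have Wilson 95% intervals, which cover counting error only, because neighbouring sites and PCR copies are not independent and each mutant is 1 library. Constitutive sites were drawn 10000 times in sets of the size of the gained set, matched on deciles of the WT SMARCA4 -log10 q. Peak numbers were compared by a two-sided exact permutation test of the difference of means, counting labelings with a difference at least as large in size, with Benjamini-Hochberg adjustment over 3 antibodies. Jaccard indices were computed in bases.

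To ask what depth and fragment length would do, the WT pileups at each site were scaled to another library, redrawn from a Poisson distribution 100 times, and called at the lowest -log10 p in that library's list. The background was scaled by the ratio of background pileups, and the site pileup by the smaller of that ratio and the ratio of fragments per kb, so that for SMARCC1 the scale was 0.622 in CBR, 0.518 in Empty replicate 1, 0.425 in DBDmut, 0.332 in delIDR1 and 0.326 in DDX4 where fragments per kb alone gave 0.872, 0.640, 0.494, 0.404 and 0.427. At its own depth this recovered 86.4% of gained sites for both subunits, so the procedure itself loses some. Code was tested on simulated data first: 3000 simulated gained sites among 12412 were all scored as simulated, and 20000 simulated pileups were recovered in 100% of cases.

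Sites named in the text were picked by a rule fixed before the data were examined: the 20 gained and 5 constitutive sites of smallest summed rank by -log10 q in the WT SMARCA4 and SMARCC1 lists, the 5 such gained sites without either subunit in each mutant, and the 5 HA peaks of highest -log10 q. Other settings fixed at the same time were a -log10 q of at least 5, lists shortened to the same number of peaks per antibody (5567 for SMARCA4, 9685 for SMARCC1 and 31745 for H3K27ac), an overlap of 50% of the shorter peak, summits within 250 bp, leaving out either Empty replicate, all sequences in the lists, and either subunit alone. A further setting, only the gained sites ranked above the median of both WT lists, was chosen after seeing the data, as was the count of sites of a single Empty replicate that WT lacked.

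No GRCh37 gene annotation or genome was used here, and coordinates were not converted, so sites are given by hg19 position without gene, exon or promoter. The comparison with gene lists, the distance to transcription start sites and the motif search planned for gained sites were not done for the same reason. Replicate numbers exist only for Empty, so samples could not be paired. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.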

Results

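Chromatin occupancy was profiled by CUT&Tag, in which an antibody directs a transposase to its target in nuclei so that fragments at bound sites are released and sequenced. The cells were AN3CA, an established human endometrial carcinoma line, carrying either an empty vector or a form of ARID1A, a large subunit of the canonical BAF (SWI/SNF) chromatin remodelling complex. The forms were wild-type ARID1A (WT), the CBR truncation, a mutant of the ARID domain (DBDmut; the ARID domain is the protein's DNA-binding domain), a truncation named delIDR1, and a hybrid carrying an intrinsically disordered region named for DDX4. Each was profiled with antibodies to SMARCA4, the ATPase of the complex, to SMARCC1, a core subunit, and to H3K27ac, a histone mark of active promoters and enhancers. The empty vector (Empty) had 2 replicates and every other construct had 1 library per antibody, so no difference between single constructs has a replicate check. DDX4 also had 1 library of the HA tag, giving 22 libraries analysed here.

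Each library came as 1 list of peaks in hg19 coordinates, with 5411 to 92136 peaks on all sequences. Peak names began with 3 different stamps, read here as sequencing runs although the labels do not say what they are. Empty replicate 1, WT, CBR, DBDmut and delIDR1 shared the first, the 4 DDX4 libraries had the second, and Empty replicate 2 had the third. The background implied by the peak statistics gave a relative depth of 0.916 to 1.95 fragments per kb for SMARCA4, 1.33 to 3.28 for SMARCC1 and 3.59 to 14.5 for H3K27ac, and 0.462 for HA. The WT libraries had 1.53, 3.28 and 4.48 fragments per kb for SMARCA4, SMARCC1 and H3K27ac, and the deepest library by far was H3K27ac of Empty replicate 2. All counts below are for chromosomes 1 to 22 and X.

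The first comparison asked whether cells with any form of ARID1A had more peaks than cells without. WT cells had 12949 SMARCA4 peaks, against 5567 and 9409 in the Empty replicates, and 23855 SMARCC1 peaks, against 13641 and 15461. DBDmut was above both Empty replicates for both subunits, with 15207 SMARCA4 and 18849 SMARCC1 peaks. CBR had 12894 SMARCA4 peaks but 11983 SMARCC1 peaks, while delIDR1 had 7130 and 10477 and DDX4 had 8784 and 9685. For H3K27ac, the 5 libraries with ARID1A had 31745 to 50885 peaks, and the Empty replicates had 36348 and 92057.

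Taken as a group, the libraries with ARID1A did not separate from Empty in peak number. For SMARCA4 the mean was 11393 ± 3324 (SD, n = 5) with ARID1A and 7488 ± 2717 (SD, n = 2) without, with p = 0.238 in a two-sided exact permutation test over 21 labelings (0.357 after Benjamini-Hochberg adjustment over 3 antibodies). For SMARCC1 the means were 14970 ± 6145 and 14551 ± 1287, with an exact p = 0.952 and the same adjusted value. For H3K27ac they were 39821 ± 7107 and 64203 ± 39392, with an exact p = 0.190 and an adjusted p of 0.357. The smallest p that 2 libraries against 5 allow is 0.0476, and the adjustment raises it unless all 3 antibodies reach it. The 5 libraries with ARID1A were also 5 different constructs, so the test had little room to show a separation. The labels do not say whether libraries came from separate cultures. Without Empty replicate 2 the H3K27ac difference turned from -24382 to 3473 peaks (-52236 without replicate 1), and without Empty replicate 1 the SMARCC1 difference turned from 418.8 to -491.2. For SMARCA4 the difference was 3905 peaks with both replicates, 1984 without replicate 1 and 5826 without replicate 2.

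**Figure D1:**
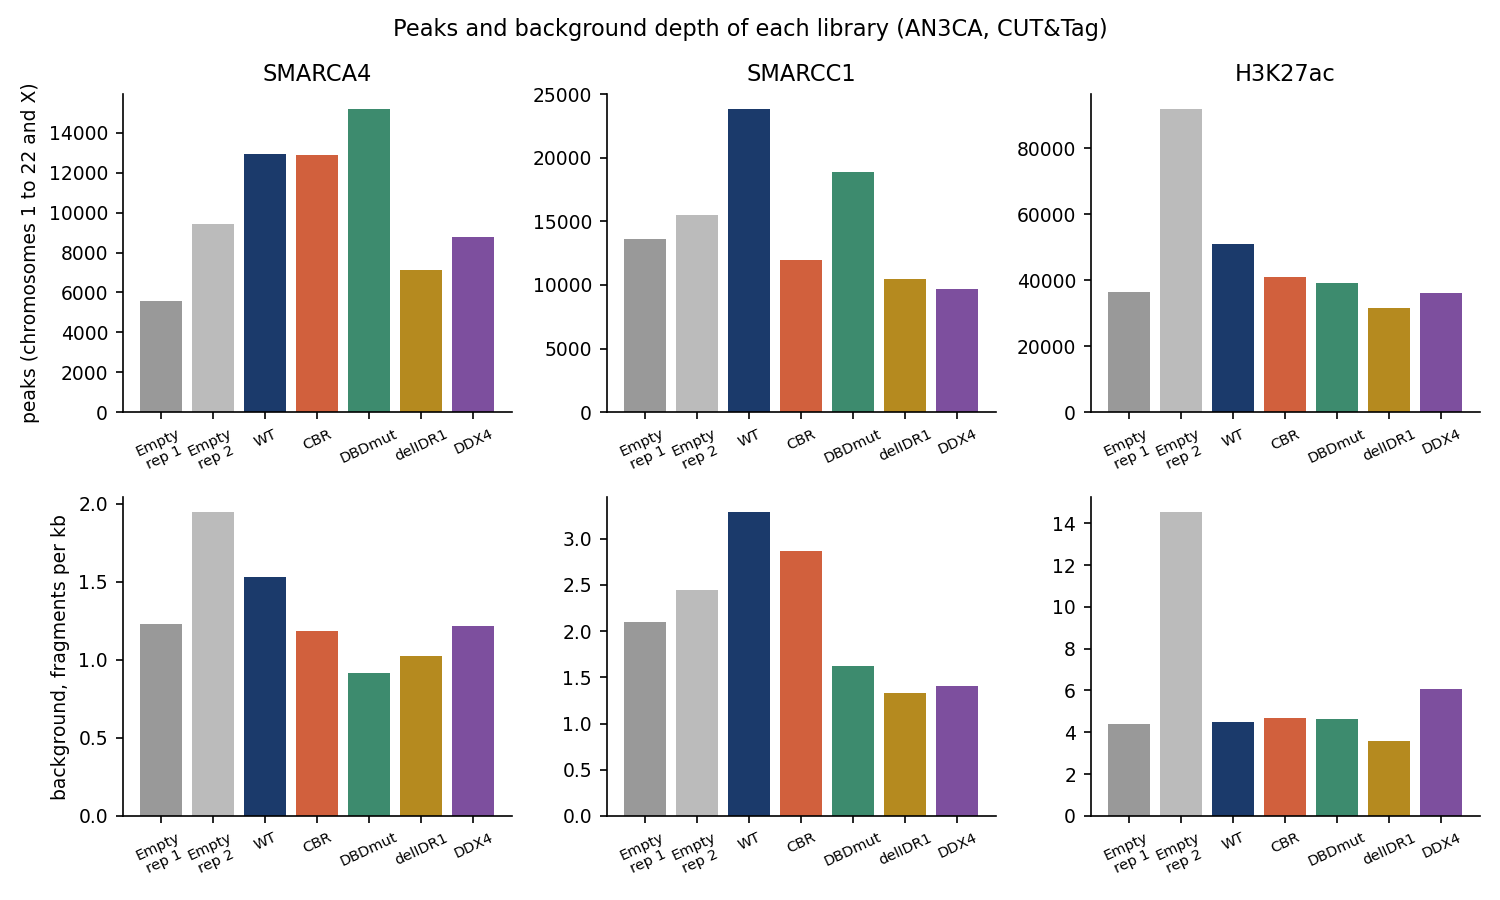
Number of peaks on chromosomes 1 to 22 and X (top row) and background depth in fragments per kb (bottom row) of each SMARCA4, SMARCC1 and H3K27ac library, 1 bar per library. WT has the most SMARCC1 peaks (23855), DBDmut the most SMARCA4 peaks (15207) at the lowest SMARCA4 depth (0.916), and Empty replicate 2 has 92057 H3K27ac peaks at 14.5 fragments per kb.

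The next comparison asked where the BAF subunits SMARCA4 and SMARCC1 were found with wild-type ARID1A and not without it. Peaks of both subunits do not show which complex held them or whether it contained ARID1A. A BAF site was a WT SMARCA4 peak that overlapped a WT SMARCC1 peak, which held for 9743 of the 12949 SMARCA4 peaks (75.2%). Of these sites, 4383 (45.0%) met no SMARCA4 or SMARCC1 peak of either Empty replicate and are called gained here. Another 2581 (26.5%) had both subunits in both Empty replicates and are called constitutive, and the remaining 2779 (28.5%) were mixed. In the other direction, 203 of the 4179 BAF sites of Empty replicate 1 (4.86%) and 1071 of the 6610 of Empty replicate 2 (16.2%) had neither subunit's peak in WT. Of 3230 sites with both subunits in both Empty replicates, a stricter set, 72 (2.23%) had neither in WT.

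The number of gained sites was far above the difference between Empty replicates. Against Empty replicate 1 alone, with the same stamp, 4842 of the WT sites were gained, and against Empty replicate 2 alone 4694 were. The same count was 174 for Empty replicate 1 against replicate 2 and 1004 for replicate 2 against replicate 1. With every list shortened to the same number of peaks, 1548 WT sites were gained, and with a single subunit as the criterion 8250 SMARCA4 or 13656 SMARCC1 peaks were.

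Gained sites were weaker than constitutive ones within the WT lists but included some of the strongest WT peaks. Their median rank was 6202 among SMARCA4 peaks and 8241 among SMARCC1 peaks, against 2740 and 2263 for constitutive sites. The gained site of smallest rank sum lay on chromosome 5 from 55972045 to 55972448, at rank 59 for SMARCA4 and 49 for SMARCC1, with the authors' fold enrichments of 23.0 and 21.2 over the local background. The next lay on chromosome 10 from 95506706 to 95507018, with a SMARCA4 fold of 19.4, on chromosome 6 from 91078712 to 91079155, with a fold of 18.9, and on chromosome 18 from 29228942 to 29229279, with a fold of 18.7. Across the 20 strongest gained sites the SMARCA4 fold ran from 13.2 to 23.0 and the rank from 59 to 338. All 20 had an H3K27ac peak in WT, while 4 had one in Empty replicate 1 and 6 in Empty replicate 2.

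The 5 strongest constitutive sites had folds of 17.9 to 63.2. They included a site on chromosome 13 from 110076479 to 110076687, 1 on chromosome 1 from 121484062 to 121485424, and sites near sequence ends on chromosome 5 from 10028 to 11776 and on chromosome X from 155259841 to 155260406. No list of artefact-prone regions was applied.

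Gained and constitutive sites were split differently over chromosomes. Neither class was compared with chromosome length, so the ratios do not say which class is the uneven one. Chromosome 19 held 111 of them (2.53%) but 232 of the constitutive sites (8.99%), a ratio of 0.478 gained per constitutive site. Chromosome 8 had the highest ratio, 2.72, with 188 gained and 69 constitutive sites. Joining sites less than 12.5 kb apart gave 40 regions with 3 or more gained sites, which held 131 sites (2.99%), and 34 regions of constitutive sites, which held 140 (5.42%).

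The region with the most gained sites spanned 21.2 kb on chromosome 5, from 138040002 to 138061210, and was chosen after its values were seen. It held 5 gained sites, all with H3K27ac in WT. Both subunits were present at 3 of the 5 sites in DBDmut and in delIDR1, at 1 in CBR and at 0 in DDX4. H3K27ac overlapped 4 of them in DBDmut and delIDR1, and 1 in CBR and DDX4, against 1 and 2 in the Empty replicates.

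**Figure D2:**
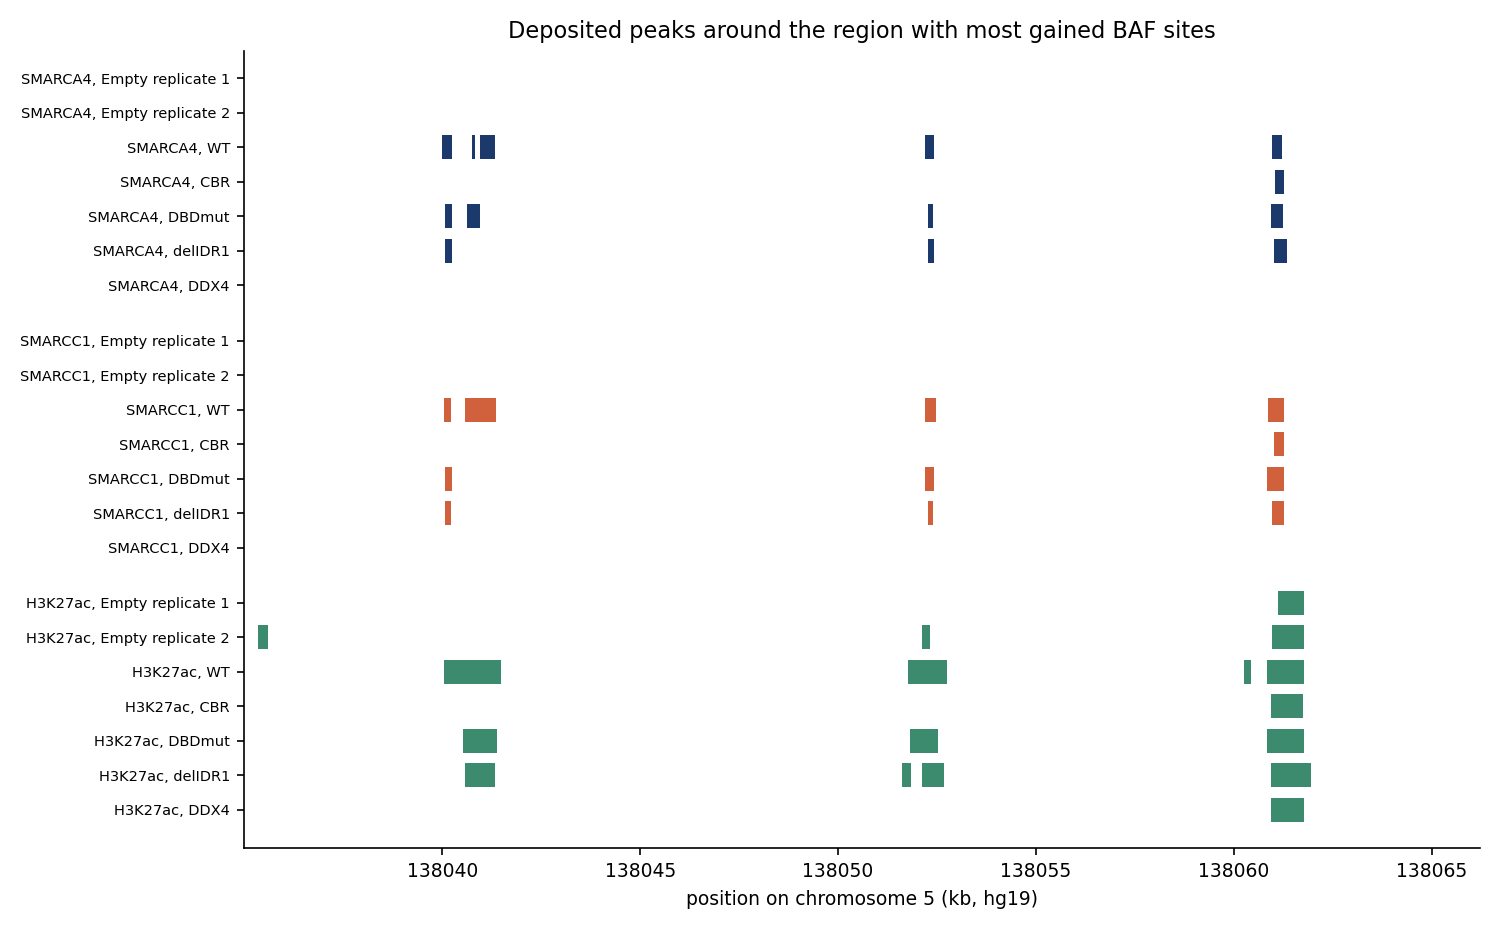
Deposited peaks of each library on chromosome 5 from 138040002 to 138061210 with 5 kb either side (x axis, kb in hg19), 1 row per library, grouped by antibody, with each block drawn to scale from a peak's start to its end. WT has 5 SMARCA4 and 4 SMARCC1 peaks there, and the Empty replicates and DDX4 have 0 of either.

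The mutants were then compared at the sites gained with WT, asking which parts of ARID1A go with BAF occupancy there. DBDmut kept both subunits at 1558 of the 4383 gained sites (35.5%, Wilson 95% interval 34.1 to 37.0). The delIDR1 truncation kept 614 (14.0%, 13.0 to 15.1), CBR kept 241 (5.50%, 4.86 to 6.21) and DDX4 kept 21 (0.479%, 0.314 to 0.731). These intervals cover counting error only. Constitutive sites were found far more often in the same libraries, in 94.2% for DBDmut, 75.4% for delIDR1, 86.1% for CBR and 87.7% for DDX4. The SMARCA4 libraries of these mutants had 0.916, 1.02, 1.19 and 1.22 fragments per kb, and the SMARCC1 libraries 1.62, 1.33, 2.87 and 1.40. Part of the missing sites is therefore expected from the libraries themselves: WT pileups thinned to each mutant's libraries were called for both subunits at 53.7%, 45.1%, 70.2% and 44.9% of gained sites. The observed shares were lower than these by 18.2 percentage points in DBDmut, 31.1 in delIDR1, 64.7 in CBR and 44.4 in DDX4. These gaps cannot exceed the thinned share and so do not rank the mutants. At constitutive sites the same thinning gave 79.3%, 74.1%, 89.7% and 73.5%. It was therefore below the observed share in DBDmut and DDX4, close to it in delIDR1 and above it in CBR. The thinned shares are rough guides to what each library could detect. They start from the WT library in which the gained sites were chosen, so they may be too high there. Without a second WT library the gaps cannot be read as loss beyond depth.

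Constitutive sites matched to the gained ones on WT SMARCA4 strength were also kept more often. Among 10000 random matched sets the median share kept was 90.9% in DBDmut, 63.6% in delIDR1, 76.3% in CBR and 83.0% in DDX4, and 0 of the sets reached down to the gained share in any mutant. Part of this gap follows from selection, since constitutive sites had to be called with both antibodies in both Empty replicates, and SMARCC1 strength was not matched (median -log10 q 22.8 at constitutive and 11.0 at gained sites). With a single subunit required, SMARCA4 peaks were at 44.9% of gained sites in DBDmut, 22.7% in delIDR1, 10.1% in CBR and 1.83% in DDX4, and SMARCC1 peaks at 51.3%, 24.1%, 11.4% and 4.77%.

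The order DBDmut, delIDR1, CBR, DDX4 held under all 10 other settings tried, but its spacing did not. With the same number of peaks per list, delIDR1 kept 27.5% and DBDmut 32.9%. With SMARCA4 or SMARCC1 peaks alone defining the sites, CBR kept 14.9% or 8.99% and DDX4 5.95% or 4.0%, and without Empty replicate 1 or 2 DDX4 kept 1.0% or 1.76%.

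At the 20 strongest gained sites, DBDmut and delIDR1 had BAF peaks at every site, so no difference between them could show. CBR and DDX4 had fewer. All 20 had both subunits in DBDmut and in delIDR1, 10 had both in CBR and 3 in DDX4. The site on chromosome 5 from 55972045 had both subunits in all 4 mutants, as did the site on chromosome 6 from 91078712 and the site on chromosome 5 from 98355798 to 98356208. The site on chromosome 10 from 95506706 to 95507018 and the site on chromosome 5 from 39518655 to 39518955 had both subunits and H3K27ac in DBDmut and delIDR1 and no peak of any of the 3 antibodies in CBR or DDX4.

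The strongest gained sites without either subunit in a given mutant ranked lower in WT for DBDmut than for the others. For DBDmut they began at SMARCA4 rank 484, on chromosome 10 from 64966781 to 64967081, a site with both subunits and H3K27ac in delIDR1. For delIDR1 they began at rank 183, on chromosome 8 from 126231552 to 126231827, where both subunits were present in DBDmut. H3K27ac was present there in delIDR1, but also in Empty replicate 1 and in CBR, DBDmut and DDX4. At the site on chromosome 15 from 31764154 to 31764347, next in order for delIDR1, that truncation lacked H3K27ac as well. For CBR and DDX4 the first such site was the one on chromosome 10 from 95506706, at rank 118.

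**Figure D3:**
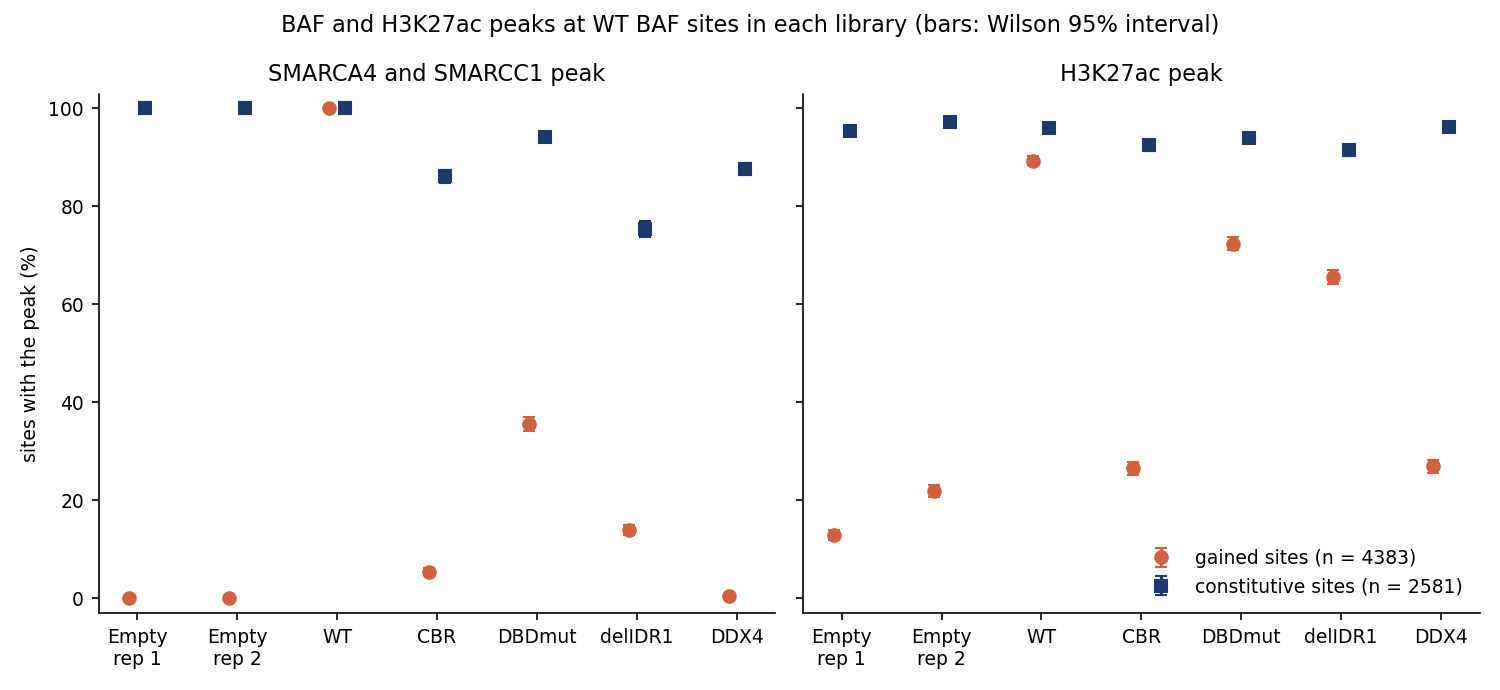
Share of the 4383 gained (circles) and 2581 constitutive (squares) sites with both SMARCA4 and SMARCC1 peaks (left) or an H3K27ac peak (right) in each library, in percent, with Wilson 95% intervals, many of them smaller than the symbols. Shares of 0 and 100% in Empty and WT on the left follow from how the sites were defined. Among the mutants the gained share is highest in DBDmut (35.5%) and lowest in DDX4 (0.479%).

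Mutants also had BAF sites of their own that neither Empty replicate had. There were 2810 in DBDmut, 821 in delIDR1, 812 in CBR and 60 in DDX4. Of these, 74.8% in delIDR1, 55.0% in DBDmut, 33.3% in DDX4 and 29.8% in CBR had both subunits in WT too. Against Empty replicate 1 or 2 alone, DBDmut had 3463 or 3236 such sites, CBR 1242 or 1231, delIDR1 992 or 960 and DDX4 286 or 135. Empty replicate 2 had 1004 against replicate 1, but the lists differ in length. As shares of each library's BAF sites these were 35.0% or 32.7%, 20.2% or 20.1%, 21.6% or 20.9%, and 5.98% or 2.82%. The share for Empty replicate 2 was 15.2%. By share, delIDR1 and CBR were close and above Empty replicate 2, and DDX4 was below it.

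DDX4 was set beside delIDR1, the truncation named for a disordered region, to ask whether the hybrid occupied sites that delIDR1 lacked. Of the 2944 gained sites with neither subunit in delIDR1, DDX4 had both subunits at 6 (0.204%, 0.0934 to 0.444). DBDmut had both at 657 of them (22.3%) and CBR at 72 (2.45%). Of the 135 constitutive sites that delIDR1 lacked, DDX4 had 81 (60.0%, 51.6 to 67.9), DBDmut 98 (72.6%) and CBR 67 (49.6%). DDX4 was the only construct with its stamp.

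The H3K27ac lists were used to ask whether gained sites carried the acetyl mark. In WT, 3914 of the 4383 gained sites (89.3%, 88.3 to 90.2) overlapped an H3K27ac peak, against 12.9% and 21.9% in the Empty replicates. The share was 72.4% in DBDmut (71.0 to 73.7) and 65.5% in delIDR1 (64.1 to 66.9), and 26.6% in CBR (25.3 to 27.9) and 26.9% in DDX4 (25.7 to 28.3). Constitutive sites had H3K27ac in 91.5% to 97.2% of cases in every library.

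Most gained sites were without the mark in Empty cells. At 3284 of them (74.9%) neither Empty replicate had an H3K27ac peak, and WT had one at 2867 of these (87.3%). DBDmut had H3K27ac at 67.8% of the 3284 and delIDR1 at 59.7%, while CBR had it at 13.0% and DDX4 at 13.4%. At the same sites both subunits were present in 34.8%, 13.4%, 2.68% and 0.0914%.

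Within each mutant, H3K27ac was more frequent at gained sites where BAF peaks were also present. In DBDmut it overlapped 93.8% of gained sites with both subunits, 80.3% of those with a single subunit and 47.9% of those with neither. The values were 95.3%, 85.0% and 53.8% in delIDR1, 83.4%, 61.7% and 18.4% in CBR, and 85.7%, 74.1% and 23.8% in DDX4, where only 21 sites had both.

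The share of gained sites kept went with the strength of the site in WT. From the strongest to the weakest 20% of gained sites by summed rank, both subunits were found at 70.5% down to 11.4% in DBDmut, 40.7% down to 1.60% in delIDR1, 12.7% down to 1.82% in CBR and 1.25% down to 0.114% in DDX4. H3K27ac at the same sites went from 90.1% to 51.7%, 86.3% to 45.3%, 38.3% to 18.0% and 42.1% to 15.6%. Among the 877 strongest of these sites, delIDR1 had both subunits at 357 and DBDmut at 618.

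**Figure D4:**
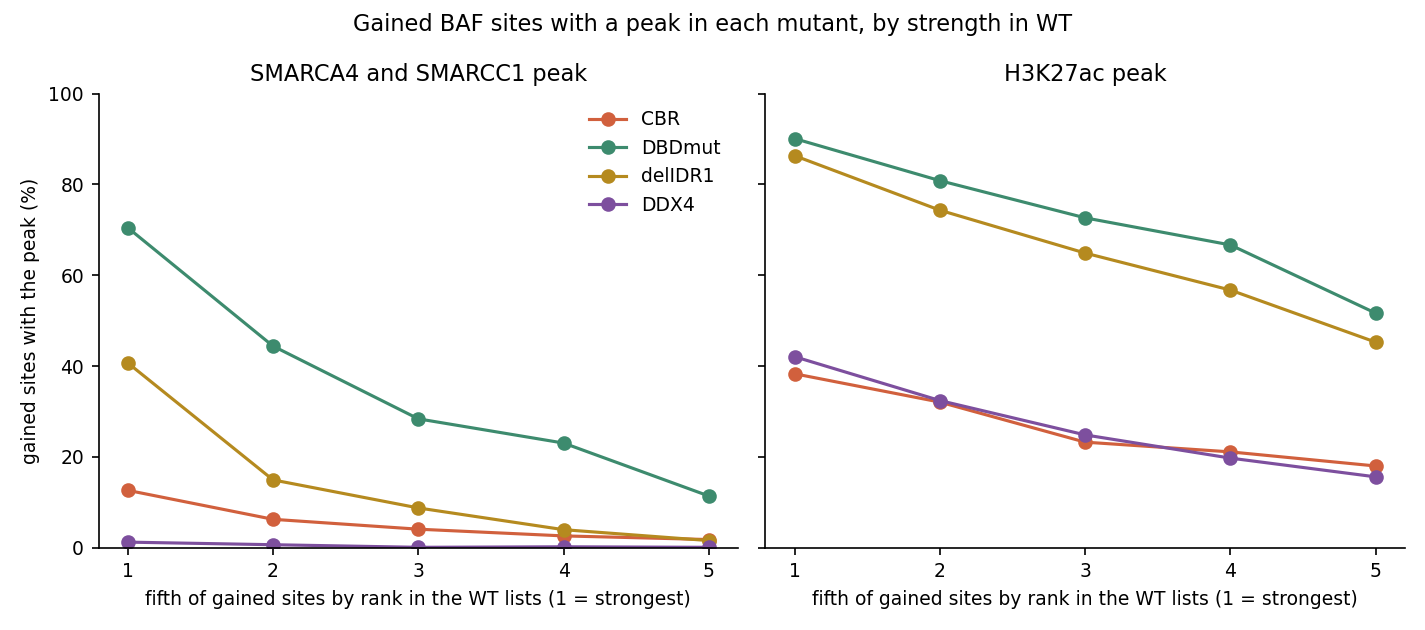
Share of gained sites, in percent, with both SMARCA4 and SMARCC1 peaks (left) or an H3K27ac peak (right) in each mutant, for 5 equal groups of sites ordered by summed rank in the WT lists, 1 point per library and group, with no error bars. In the strongest group DBDmut has both subunits at 70.5% of sites and DDX4 at 1.25%, and H3K27ac stands at 90.1% in DBDmut and 86.3% in delIDR1.

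Over the genome, 20331 of the 50885 WT H3K27ac peaks (40.0%) met no H3K27ac peak of either Empty replicate. Of these gained peaks, 6743 (33.2%) overlapped a WT SMARCA4 or SMARCC1 peak, against 51.4% of the WT H3K27ac peaks that both Empty replicates had. DBDmut had 41.2% of the gained peaks (40.5 to 41.9) and delIDR1 33.1% (32.4 to 33.7), against 7.70% in CBR (7.34 to 8.08) and 7.50% in DDX4 (7.15 to 7.87). Peaks of WT that both Empty replicates had were found in 87.7%, 77.7%, 79.7% and 91.6% of cases.

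Gained H3K27ac peaks with a WT BAF peak were found in the mutants more often than those without, though peak strength was not matched. The shares were 64.5% and 29.6% in DBDmut, 54.8% and 22.3% in delIDR1, 11.5% and 5.82% in CBR, and 10.9% and 5.79% in DDX4. The Empty replicates differed strongly for this antibody: 69355 peaks of replicate 2 (75.3%) were absent from replicate 1. Against replicate 1 alone 29414 WT peaks were gained, and with the same number of peaks per list 12235 were.

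Some H3K27ac peaks were found without ARID1A and not with it. Of 28511 peaks of Empty replicate 1 that replicate 2 shared, 5758 (20.2%) had no H3K27ac peak in WT. Of these 5758, DDX4 had 46.2%, CBR 35.0%, DBDmut 30.8% and delIDR1 20.6%, the last with the fewest H3K27ac fragments per kb, 3.59.

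The HA library, directed at the tag, was compared with the BAF lists. Of its 5390 peaks, 3608 (66.9%, 65.7 to 68.2) overlapped a SMARCA4 or SMARCC1 peak of DDX4 cells, and 77.1% an H3K27ac peak. The share was 67.6% with the WT lists and 62.6% and 71.9% with those of the Empty replicates, whose cells carried the empty vector, so overlap with BAF peaks did not set DDX4 cells apart. HA peaks were at 142 gained sites (3.24%, 2.76 to 3.81) and at 1749 constitutive sites (67.8%, 65.9 to 69.5). The HA peak of highest -log10 q lay on chromosome 13 from 110076484 to 110076679, with a fold of 37.2, at the constitutive site named above. The next were on chromosome 11 from 10530754 to 10531539 and on chromosome 1 from 121484064 to 121485424, followed by peaks on chromosome 5 from 79946607 to 79947709 and on chromosome 1 from 567264 to 568179. The peaks from 110076484 and 121484064 overlapped constitutive sites, which Empty cells had too. As no list of artefact-prone regions was applied, these strongest HA peaks are not shown to be sites of the tagged protein. No HA library of another construct or of Empty cells was analysed here.

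Similarity of whole peak lists was measured by the Jaccard index, the bases shared by a pair of lists over the bases in either. DBDmut was the list nearest to WT for all 3 antibodies, with 0.288 for SMARCA4, 0.356 for SMARCC1 and 0.488 for H3K27ac. The delIDR1 list came next for SMARCA4 (0.269) and H3K27ac (0.422). For SMARCC1 its index (0.240) was below those of Empty replicates 1 and 2 (0.252 and 0.271). With the same number of peaks per list this order turned, with 0.326 for delIDR1 against 0.310 and 0.307. The Empty replicates had indices of 0.213, 0.361 and 0.203 with each other, so that for SMARCA4 and H3K27ac they were no nearer to each other than Empty replicate 1 was to WT (0.224 and 0.312). The SMARCA4 pair with the highest index was Empty replicate 2 and DDX4, at 0.390, and these lists also had the widest SMARCA4 peaks, with medians of 306 and 287 bp against 144 to 184 bp in the others.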

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

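The CBR truncation stood on opposite sides of both Empty replicates for the 2 BAF subunits. Its 12894 SMARCA4 peaks were more than the 5567 and 9409 of Empty, and its 11983 SMARCC1 peaks were fewer than the 13641 and 15461 of Empty. The difference between the subunits was not tested, since CBR had 1 library per antibody. Its SMARCA4 library was shallower than both Empty ones (1.19 against 1.23 and 1.95 fragments per kb). Its SMARCC1 library had more fragments per kb than both (2.87 against 2.10 and 2.45), but its background pileup of 0.278 lay between their 0.231 and 0.365.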

How the results depend on the processing

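Over the 84 values under other settings, 49 stayed within the limit set for them and 35 moved. The limit was 1.5 times for a count, the main 95% interval for a share, the side of the test's threshold for a difference in mean peak number, and for such a difference without an Empty replicate its sign and 1 SD of the Empty counts. Dropping 1 of 2 replicates cannot shift it by that SD, so there only a change of sign counted as moved. The subset of stronger sites was chosen after seeing the data. The order DBDmut, delIDR1, CBR, DDX4 in gained sites kept held in all 10 other settings. Counts that differed by more than 1.5 times were the gained sites with the same number of peaks per list (1548), with SMARCA4 peaks alone (8250) and with SMARCC1 peaks alone (13656), and the gained H3K27ac peaks with the same number per list (12235). Shorter lists drop weaker sites, and a single subunit admits more. With the same number of peaks, gained sites kept were 6.27% in CBR, 32.9% in DBDmut and 27.5% in delIDR1, H3K27ac in WT was at 93.3% of gained sites and HA overlap was 63.1%. With SMARCA4 alone, CBR kept 14.9%, delIDR1 18.0% and DDX4 5.95%, and H3K27ac in WT was at 73.8%. With SMARCC1 alone, CBR kept 8.99%, DBDmut 30.0%, delIDR1 12.7% and DDX4 4.0%, with H3K27ac at 69.2%. At gained sites above the median of both WT lists, CBR kept 11.6%, DBDmut 67.0%, delIDR1 36.7% and DDX4 1.25%. A -log10 q of at least 5 gave 90.8% for H3K27ac in WT and 89.7% for HA overlap. An overlap of 50% gave 33.6% for DBDmut and 63.3% for HA, and summits within 250 bp gave 83.8% for H3K27ac and 64.0% for HA. Leaving out either Empty replicate gave 7.66% to 7.82% for CBR, 1.0% to 1.76% for DDX4 and 87.9% to 88.8% for H3K27ac in WT. The difference in mean peak number between ARID1A and Empty then ran from 1984 to 5826 for SMARCA4, from -491.2 to 1329 for SMARCC1 and from -52236 to 3473 for H3K27ac, as values with no test. Apart from these constructions the cause was not tested. All sequences in the lists moved no value beyond its limit. The distance to transcription start sites was not run for want of a GRCh37 annotation. No paired analysis was possible because only Empty has more than 1 replicate. Depth limits the weakest sites, and fragments per kb ran from 0.916 to 1.95 for SMARCA4 and from 1.33 to 3.28 for SMARCC1.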

Other observations

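The tests of the sequencing run, of weaker enrichment in Empty, of detection in the DDX4 run and of depth from observed shares were chosen after the results were seen.

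Mutants kept overlapping sets of gained sites. Of the 614 sites kept in delIDR1, 474 (77.2%) were also kept in DBDmut, against 354.5 expected from independent choice within deciles of WT strength and 218.3 without that matching. For H3K27ac at gained sites, CBR and DDX4 shared 797 of 1164 and 1181 sites, against 347.2 expected within deciles. Only 426 of the CBR sites and 439 of the DDX4 sites were among the 3284 with no H3K27ac in Empty. The expected count does not allow for acetylation already present in Empty and is too low for that reason. All these sets share the same WT and Empty libraries, so part of the excess can come from them.

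Wild-type ARID1A had more BAF sites than the empty vector. Depth is argued against by the SMARCA4 library of Empty replicate 2, which was deeper than that of WT (1.95 against 1.53 fragments per kb) and had a peak at 38.7% of the WT BAF sites. Thinning WT to the Empty depth left a share at least 39.0 percentage points above the observed one. That share may be too high, as the sites were chosen by their calls in the same WT library. A run effect is argued against by 4842 gained sites within the same run, if the stamps in the peak names mark runs, and uniformly weaker enrichment in Empty by the WT BAF sites above the median of both WT lists, of which at most 55.2% were found in an Empty replicate. A dependence of these sites on ARID1A is a hypothesis consistent with these values, and with 1 WT library per antibody variation between cultures stays open.

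The delIDR1 truncation had H3K27ac at 65.5% of gained sites and both BAF subunits at 14.0%. Acetylation already present without ARID1A is argued against, since at gained sites with no H3K27ac in Empty delIDR1 exceeded CBR by 46.7 percentage points. For SMARCA4, low depth is argued against by DBDmut, whose shallower library had SMARCA4 at 22.2 percentage points more of the gained sites. However, delIDR1 also had SMARCA4 at fewer constitutive sites (81.2% against 95.4% in DBDmut). Its share of these with both subunits, 75.4%, was the lowest of the mutants. Poorer detection in the delIDR1 libraries, apart from depth, is therefore not separated from the truncation. For SMARCC1 there is no such comparison, since delIDR1 had the shallowest library (1.33 fragments per kb, against 1.62 in DBDmut). Thinned WT pileups left 31.1 percentage points more than observed for both subunits. The gained sites were chosen in that WT library, so this gap cannot exclude depth. With the same number of peaks per list, however, delIDR1 kept 27.5% of gained sites and DBDmut 32.9%, so depth may account for part of the low share. What stays open is that 1 histone antibody may be easier to call than 2 subunits: at newly acetylated gained sites the ratio of H3K27ac to BAF share was 4.47 in delIDR1 and 5.51 in CBR, a ratio of 0.811 between them, but 1.99 in DBDmut (the DDX4 ratio, 143, rests on 3 BAF sites of 2867 and is no guide). By the comparison set in advance, which used CBR alone, the values go with a gap set by detection. DBDmut was not part of that comparison. The ratio rises as the BAF share nears 0 and falls as it grows. CBR had both subunits at 2.65% of these sites and DBDmut at 37.8%, so neither ratio can decide. Where neither subunit was called, H3K27ac was at 54.2% of these sites in delIDR1, 49.2% in DBDmut, 13.9% in DDX4 and 10.2% in CBR. A gap set by detection stays open, as does acetylation without BAF occupancy in delIDR1.

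DDX4 kept almost no gained sites. Depth is argued against by delIDR1, which kept 13.5 percentage points more with a shallower SMARCA4 library. Its SMARCC1 library had about the same depth (1.33 against 1.40 fragments per kb, background pileups of 0.148 and 0.146). Thinning left 44.4 percentage points more than observed, but it starts from the WT library in which the gained sites were chosen. DDX4 kept 87.7% of constitutive sites, above delIDR1 and CBR, which argues against a loss of detection in its run at such sites only. Constitutive sites were stronger than gained ones (median SMARCC1 -log10 q 22.8 against 11.0). They also had to be called in Empty replicate 2, whose SMARCA4 list was the nearest to that of DDX4 (Jaccard index 0.390). The share therefore cannot show that detection at gained sites was intact. H3K27ac was at 26.9% of gained sites in DDX4, near CBR (26.6%) and above the Empty replicates (12.9% and 21.9%). HA was at 3.24% of them, in a library of 0.462 fragments per kb with no other HA library to set it against. The hybrid itself, its expression level and an effect of its run limited to these sites stay open and untested, as no WT library shared its stamp and protein levels were not analysed here.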
